A study of Mus musculus with 3 samples.

How the data were processed

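Total RNA of mouse neural stem cells (NSCs) labelled Dnmt3a knockout (KO) was compared with RNA of wild-type (WT) NSCs on 3 two-colour Agilent 4x44K mouse arrays. Per the labels, each array was 1 of 3 biological replicates, the NSCs had been derived from mouse embryonic stem cells, and RNA was extracted with Trizol and amplified to labelled cRNA with an Agilent low-input kit. The RNA labelled KO carried Cy3 (green) and the RNA labelled WT carried Cy5 (red) on all 3 arrays. No array had the dyes exchanged, so a bias of single probes toward 1 dye could not be separated from genotype. All 3 arrays lay on 1 slide and were scanned on 1 day.

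Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 9.5.3.1, and the probe positions they give are on mouse build mm7. Per the file headers the spot and local background signals are raw intensity values. The deposited processed signals are intensity values after the scanner software's own background correction, linear and lowess dye normalization. Per the file headers the scanner's log ratio is a log10 ratio of red over green, and it was used only to check scale and direction. The authors also deposited a value table, which was set against the scanner values of the same arrays. Its columns correlated with the scanner's log2 ratio of red over green at r = -0.998, -0.996 and -0.992 across features, with slopes of -0.999, -1.03 and -0.972. The authors' table was therefore read as a log2 ratio of labelled KO over labelled WT, the same direction as used here. Its column medians were 0.0276 on each array, and how the authors had centred or scaled it is not given in the sources used here.

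Each array held 45018 features, of which 43379 were spots other than controls, for 41174 distinct probes. Mean spot signals and median local backgrounds were corrected with limma's normexp method (offset 50, limma 3.58.1 in R 4.3.3). The offset is added to every corrected signal and draws the ratios of dim spots toward 0. Per array and channel, the median spot signal was 75.7 to 105 and the median background 39.5 to 43. Log ratios were normalized by loess within each array with control spots at weight 0, turned to labelled KO over labelled WT from the dyes in the labels, and averaged over the spots of a probe. Control spots and spots carrying the scanner's outlier marks were left out, and saturated spots were kept. There were 170, 173 and 242 marked spots on arrays 1, 2 and 3.

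The normexp model was first fitted on all spots. After its results had been seen, between 9 and 15 spots per channel, all marked as background outliers, were found far below their local background, and the background mean fitted with them lay between -489 and -167. Fitted on the unmarked spots, it lay between -4.66 and 1.04. The fit on unmarked spots was then taken for all values reported here unless another is named. This choice was made after seeing the data and raised the number of genes past the threshold from 2332 higher and 3119 lower to 4067 higher and 4593 lower, so both sets of counts are given.

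A probe was tested if it was well above background in the channel labelled KO on all 3 arrays or in the channel labelled WT on all 3 arrays, which kept 26626 probes. Of all 41174 probes on the array, 22951 were named through the accession in the files and 9768 through the symbol or a synonym, and 8455 kept the name in the file. Of several probes of a gene, the 1 with the highest average intensity stood for the gene, which left 18033 genes. Among 3352 genes past the threshold with more than 1 tested probe, 211 had another probe past the threshold in the opposite direction. The fold of a gene whose probes were not well above background on any array in 1 channel was given only as a lower bound. That bound set the mean of the bright channel against a mean that took, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background, after loess and Aquantile normalization. Where the dim probe's own signal was the higher on all arrays, the bound equals the measured ratio. The bounds make no allowance for the spread between arrays and are open to dye bias.

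Between 63.6% and 65.0% of probes were well above background in the channel labelled KO, and between 65.5% and 68.8% in the channel labelled WT. Saturated spots numbered 1, 13 and 4 in the channel labelled KO on arrays 1, 2 and 3, and 172, 126 and 111 in the channel labelled WT. The number of arrays limits the precision.

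The mean log2 ratio of the 3 arrays was tested against 0 with limma (lmFit and eBayes, two-sided, 2 residual degrees of freedom per gene), and Benjamini-Hochberg adjusted p under 0.05 over all 18033 genes was the threshold. The ratio within an array pairs the RNA labelled KO with the RNA labelled WT of the same replicate number. Gene lists were tested with limma's camera, which compares the members of a list with all other tested genes, at a preset correlation between genes of 0.01, with at least 5 tested members and adjustment over the lists. Each list was also tested with a correlation estimated from the data, and with limma's fry, which asks whether a list's genes move on balance one way without comparing them with other genes. The 38 lists held 964 distinct genes, of which 937 were on the array.

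The lists, the test, the threshold and the rule for named genes were fixed before the data were examined. The rule named Dnmt3a and the DNA methylation machinery whatever their result. It also named the 10 genes with the largest ratio each way among those past the threshold and well above background in both channels on all 3 arrays, and the 5 largest lower bounds each way. From each list it took up to 4 members past the threshold with the largest change, and it added Nes, Sox2, Gfap, S100b, Olig2, Tubb3, Mki67 and Cdkn1a. It passed over genes known only by a clone, an accession or a probe name. Some genes that the rule takes in are not reported here, and none was put in their place. Other list members named below were chosen after their values had been seen.

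The alternatives were no background correction, the scanner's processed signals, median centring in place of loess, scaling between arrays, the authors' table, no filter or a stricter filter on dim probes, all probes averaged or tested singly, another variance model, unpaired channels, stricter thresholds, other settings of the list tests, and leaving out each replicate. The first fit of normexp, on all spots, became an alternative once the fit on unmarked spots had been chosen. That choice, and leaving out genes saturated on any array, came after seeing the data.

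The limma and camera steps were tested on log ratios simulated with the spread of these arrays, each gene drawn independently. Background correction, loess, the filter on dim probes and the choice of probe were not simulated. All 50 genes given a log2 change of 0.25, and all 50 at each of 0.5, 1 and 2, were called in the right direction. Over 20 simulations a mean of 9.65% of the calls were false, and 16.0% in the highest, above the nominal share of the adjustment. A simulated list given a shift of -0.3 was called by camera with the preset correlation and was not called with an estimated correlation.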

Results

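RNA from mouse neural stem cells labelled Dnmt3a knockout (KO) was hybridised against RNA from cells labelled wild type (WT) on 3 two-colour arrays, 1 per biological replicate. Neural stem cells (NSCs) are dividing precursors of neurons, astrocytes and oligodendrocytes, and these were grown with EGF and bFGF after derivation from embryonic stem cells. Dnmt3a encodes an enzyme that places new methyl groups on DNA. Expression was measured for 18033 genes as the log2 ratio of labelled KO over labelled WT, with 3 arrays behind each value. The log2 ratios of the arrays correlated across genes at r = 0.887 for replicates 1 and 2, 0.892 for 1 and 3 and 0.914 for 2 and 3, though genes are not independent replicates. The median SD of a gene's ratio between arrays was 0.0558. Between spots of 1 probe within an array it was 0.061 to 0.069, over 188 probes spotted 10 times. For those probes the median SD between arrays of the mean of 10 spots was 0.040. The p-values below measure only the spread between these samples.

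The comparison asked which genes differ in expression between NSCs without Dnmt3a and wild-type NSCs, in a study of the proliferation and differentiation of these cells. Dnmt3a itself was measured first, and it went against its label. Its brightest probe, A_52_P76146 on chromosome 12 from 3825243 to 3826024 (mm7), had a log2 ratio of 1.07, 0.97 and 0.92 on arrays 1, 2 and 3. Its mean was 0.99 ± 0.08 (SD, n = 3), or 1.99-fold higher in the RNA labelled KO (limma, adjusted p = 9.1e-07). Probe A_52_P169048, from 3826602 to 3826661, was higher by 0.61 ± 0.03, and probe A_52_P30497, from 3830965 to 3831024, by 0.76 ± 0.04. The labels do not say which part of the gene was deleted, so a probe outside it would not show the loss. Under the normexp fit on all spots the brightest probe was at 0.87 and the median of the 3 probes at 0.23. Every direction below is therefore given between the RNA labelled KO and the RNA labelled WT, and would turn if the labels of the channels were exchanged.

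**Figure D1:**
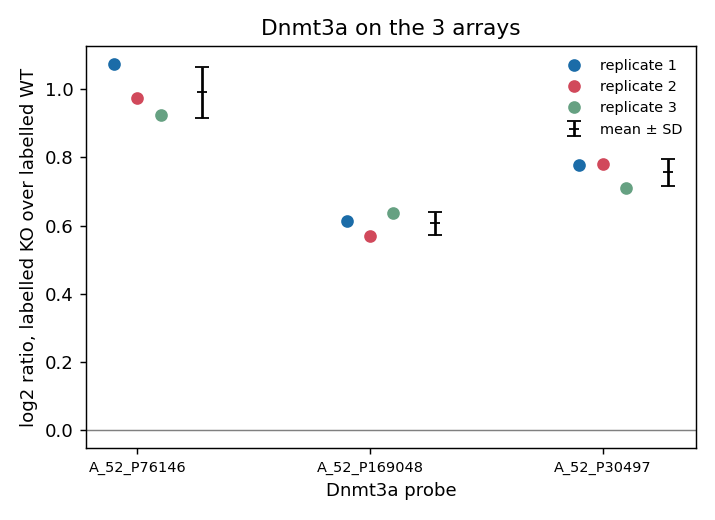
The vertical axis is the log2 ratio of labelled KO over labelled WT for each of the 3 Dnmt3a probes on the horizontal axis. Coloured points are the 3 arrays and the black bars are the mean ± SD. All points lie above 0, with means of 0.99, 0.61 and 0.76.

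In the RNA labelled KO, targets of the p53 tumour suppressor were higher, and genes of the interferon response, mitosis, DNA replication, amino acid stress and the germline were lower, by camera with its preset correlation. None of these 6 list calls held with an estimated correlation, at adjusted p = 0.49 to 0.57. That setting also missed a simulated list of independent genes shifted by -0.3. The simulation held no correlation between genes, so it cannot show that the preset of 0.01 is high enough for real lists. Whether these calls hold stays undecided. The germline call was also lost with median centring (adjusted p = 0.27). Among the largest differences were Mmp3, a matrix-degrading protease, 8.05-fold higher, and Spp1, which encodes osteopontin, 5.77-fold higher. Thbs4, an extracellular matrix protein, was 11.1-fold lower, and Crym, a thyroid hormone binding protein, was 10.4-fold lower. Most differences were small as measured, with a median absolute log2 ratio of 0.20 among genes past the threshold. The offset in the background correction draws the ratios of dim genes toward 0, so their differences may be larger than the values given.

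Of the 18033 genes, 4067 were higher and 4593 were lower in the RNA labelled KO (limma, adjusted p under 0.05). At least 2-fold differences numbered 86 higher and 124 lower, and at least 1.5-fold differences 352 higher and 367 lower. The split between higher and lower rested on loess normalization. With each array's ratios only centred on their median, the median of all genes moved to -0.26, and 734 genes were higher and 9398 lower. With normexp fitted on all spots, 2332 were higher and 3119 lower, and the fit used here was chosen after those counts had been seen.

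**Figure D2:**
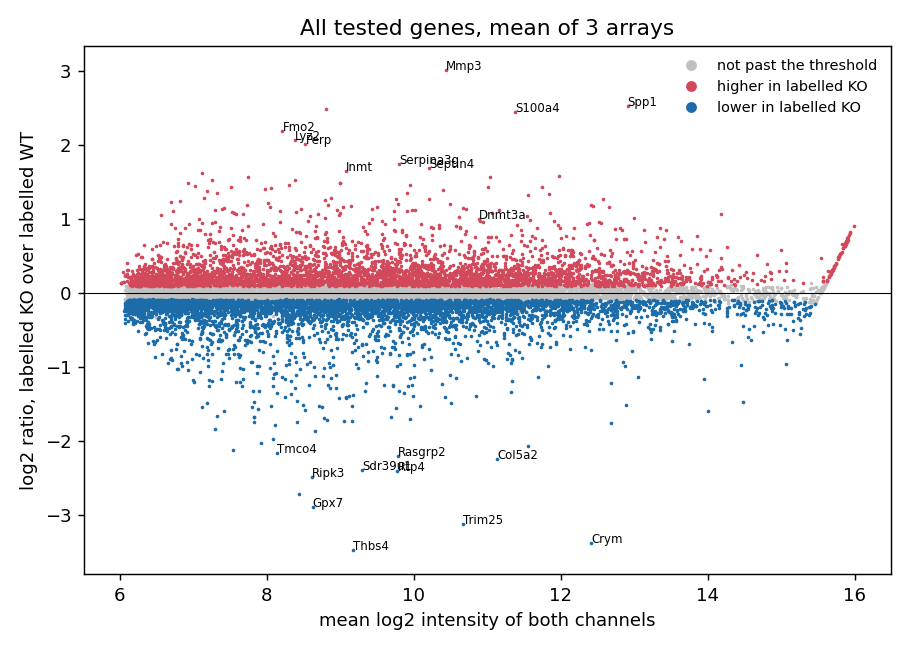
The horizontal axis is the mean log2 intensity of both channels and the vertical axis the mean log2 ratio of labelled KO over labelled WT, with 1 point per tested gene, coloured by its call. The named points include Mmp3 at 3.01 and Thbs4 at -3.47. The rising line of points at the far right holds genes saturated in the channel labelled WT, whose ratios are not measured differences.

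The genes with the largest increase were each well above background in both channels on all 3 arrays. They included Mmp3 at 3.01 ± 0.06 (SD, n = 3, adjusted p = 8.1e-09), Spp1 at 2.53 ± 0.02 and S100a4, a calcium-binding protein, at 2.43 ± 0.06. Others were the monooxygenase Fmo2 at 2.19, the lysozyme gene Lyz2 at 2.07, Perp at 2.00, the protease inhibitor Serpina3g at 1.74, Septin4 at 1.69 and the methyltransferase Inmt at 1.64. Mmp3 was probed on chromosome 9 from 7453874 to 7453933 and Spp1 on chromosome 5 from 103631152 to 103631211 (mm7).

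The 10 largest decreases began with Thbs4 at -3.47 ± 0.10 (adjusted p = 8.1e-09), probed on chromosome 13 from 89814063 to 89814004, and Crym at -3.37 ± 0.01, on chromosome 7 from 116108798 to 116108739 (mm7). Trim25, a ubiquitin ligase of antiviral sensing, was at -3.12 ± 0.14, the peroxidase Gpx7 at -2.89 ± 0.07 and Ripk3, a kinase of necroptosis, at -2.48 ± 0.03. Rtp4 was at -2.40 ± 0.47, Sdr39u1 at -2.40, the collagen gene Col5a2 at -2.24, Rasgrp2 at -2.21 and Tmco4 at -2.16. All of these genes, higher and lower, went the same way on all 3 arrays, which their selection on those same arrays all but required.

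Another 28 genes were well above background in the channel labelled KO and on no array in the channel labelled WT. The largest bounds were at least 1.41-fold for Mcpt8 and Ces2g, at least 1.39-fold for Colec10, at least 1.28-fold for S100a8 and at least 1.23-fold for Glyat. The converse held for 150 genes by the probe that stood for them, and for 6 of these, Pax1 and Adam33 among them, another probe was well above background in the channel labelled KO, so no bound is given for those. Of the others named by the rule, Arhgap30 was at least 1.84-fold lower in the RNA labelled KO, Slc25a31 at least 1.81-fold and Syce1 at least 1.61-fold. For Arhgap30, Syce1 and Colec10 the bound equals the measured ratio, and no bound here allows for the spread between arrays.

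The DNA methylation machinery list had 6 of 23 members higher, 10 lower and 7 not past the threshold, and the counts were 6 and 10 adjusted over the list alone. Its members split both ways, with a mean of 0.10, a median of -0.078 and no call by camera (adjusted p = 0.85). Gadd45g, a stress-inducible gene, was at 1.43 ± 0.11, Gadd45b at 1.03 ± 0.15, the cytidine deaminase gene Apobec1 at 0.55 and the methyl-CpG reader Mbd1 at 0.42. Gadd45a was at 0.11. Lower members included Uhrf1, which guides Dnmt1 to replicating DNA, at -0.39, Uhrf2 at -0.29, Trdmt1 at -0.27, Mbd2 at -0.22 and the maintenance methyltransferase Dnmt1 at -0.21. Tdg at -0.15, Tet2 at -0.14, Dnmt3b at -0.14, Tet3 at -0.13 and Zbtb33 at -0.12 were also lower, though another Tet3 probe was higher. Mbd3 at 0.14, Tet1 at -0.088, Smug1 at -0.078 and Dnmt3l at -0.011 were not past the threshold, nor was Mbd4. Mbd3 and Gadd45a turned negative, and Mbd1 stood at -0.0084, with median centring, where the all-gene median was -0.26.

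**Figure D3:**
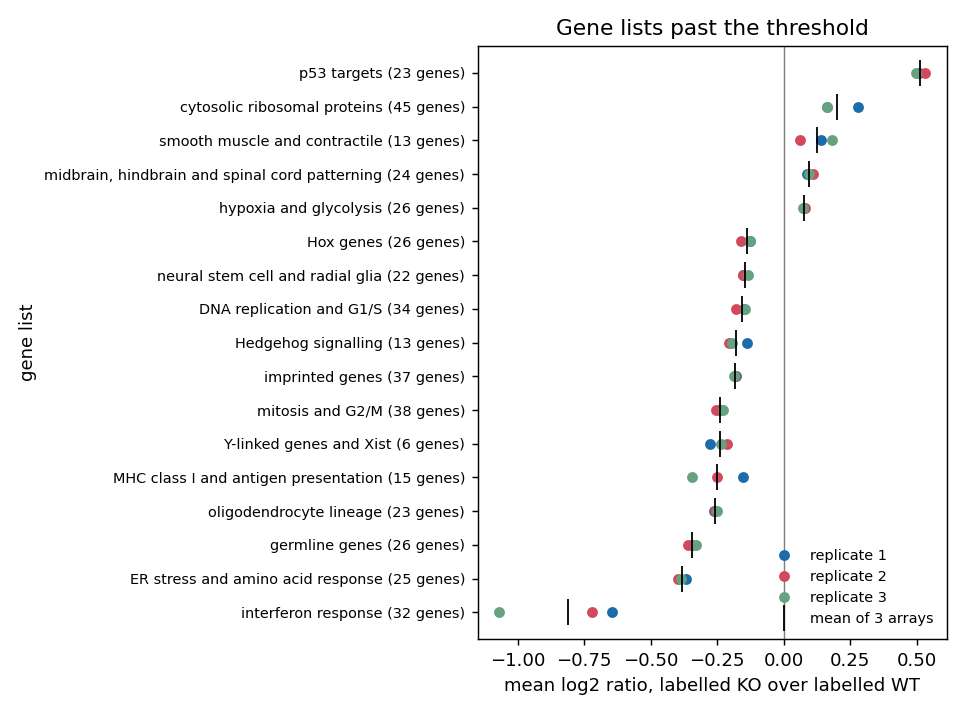
The horizontal axis is the mean log2 ratio of labelled KO over labelled WT of the tested genes of each list past camera's threshold, with lists on the vertical axis. Points are the 3 arrays and the black bar is their mean. The p53 targets stand at 0.51 and the interferon response at -0.81, and the value of the ribosomal list rests on saturated spots. With median centring camera's direction turned for the oligodendrocyte, Hox, hypoxia, ribosomal and Y-linked lists. None of them was past the threshold in the new direction (camera, adjusted p = 0.061 to 0.98).

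In all, 17 of the 38 lists were past the threshold with camera's preset correlation. With an estimated correlation, the setting that missed the simulated list, 0 were. Under the fit of normexp on all spots 10 lists were, and all 10 were among the 17. Those 10 were the p53, mitosis, DNA replication, interferon, amino acid stress, germline, imprinted, smooth muscle, hindbrain patterning and ribosomal lists. Their means lay nearer 0 under that fit for all but smooth muscle, with p53 targets at 0.39, the interferon response at -0.52, the germline at -0.11 and hindbrain patterning at 0.054.

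Among 23 tested p53 targets, genes that p53 activates after DNA damage or other stress, 20 were higher, 2 lower and 1 not past the threshold, with 20 and 2 adjusted over the list alone. Their mean was 0.51 (camera, adjusted p = 6.5e-09; adjusted p = 0.49 with an estimated correlation). Perp, a membrane protein of p53-dependent death, was at 2.00 ± 0.06, Trp53inp1 at 1.16 ± 0.03, Pmaip1, which encodes the death protein Noxa, at 1.09 ± 0.08 and Cdkn1a, which encodes the cell cycle inhibitor p21, at 0.98 ± 0.07. Mdm2, which encodes the ligase that degrades p53, was at 0.75, and the lower members were Plk2 at -0.40 and Tigar at -0.15.

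The mitosis list had 30 of 38 members lower, 0 higher and 8 not past the threshold, with 34 lower and 1 higher adjusted over the list alone. Its mean was -0.24 (camera, adjusted p = 1.0e-08; adjusted p = 0.49 with an estimated correlation). Cenpf was at -0.54 ± 0.05, Ccna2, which encodes cyclin A, at -0.51 ± 0.03, Birc5, which encodes survivin, at -0.49 ± 0.04 and Cenpe at -0.42 ± 0.04. Mki67, the gene of the proliferation antigen Ki-67, was at -0.24. Of 34 DNA replication genes, 23 were lower, 1 was higher and 10 were not past the threshold, with the same 23 and 1 counts adjusted over the list alone. Their mean was -0.16 (camera, adjusted p = 7.1e-05; adjusted p = 0.49 with an estimated correlation). E2f2 was at -0.57, the replication clamp Pcna at -0.46, E2f1 at -0.43 and the primase subunit Prim1 at -0.30.

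Inhibitors of the cell cycle and G1 regulators were mixed. Of 15 CDK inhibitor and arrest genes, 7 were higher, 6 lower and 2 not past the threshold, with a mean of 0.16, a median near 0 and camera's adjusted p = 0.37. Cdkn2a was at 0.90 ± 0.18, Cdkn2b at 0.85 ± 0.02 and Cdkn1c at -0.68 ± 0.10. Of 22 G1 cyclins and growth regulators, 10 were higher, 6 lower and 6 not past the threshold (camera, adjusted p = 0.28). The G1 cyclin Ccnd1 was at 1.26, Fgfr2 at 0.33 and Id1 at 0.32, while the EGF receptor gene Egfr was at -0.66. Id1 stood at -0.17, not past the threshold, with median centring, where the all-gene median was -0.26.

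The interferon response list had 27 of 32 members lower, 2 higher and 3 not past the threshold, with 28 lower and 3 higher adjusted over the list alone. Its mean was -0.81, and -0.64, -0.72 and -1.07 on arrays 1, 2 and 3 (camera, adjusted p = 2.3e-08; adjusted p = 0.57 with an estimated correlation). With normexp fitted on all spots the mean was -0.52 (adjusted p = 2.4e-05). Besides Trim25 and Rtp4, the antiviral genes Oas1a at -1.53 ± 0.20 and Oasl2 at -1.39 ± 0.47 fell. The higher members were Ifitm1 at 0.50 and Ifi27 at 0.34, where another Ifi27 probe was lower. Of 15 genes of MHC class I and antigen presentation, 9 were lower, 2 higher and 4 not past the threshold, with 9 and 2 adjusted over the list alone (mean -0.25, camera, adjusted p = 0.045; adjusted p = 0.57 with an estimated correlation). Psmb8 of the immunoproteasome was at -0.93, H2-K1 at -0.88, H2-D1 at -0.73 and H2-T23 at -0.56. This list was not past the threshold with the authors' values, with the scanner's processed signals, with normexp fitted on all spots or without replicate 3, where adjusted p = 0.074.

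Of 25 genes of ER stress and the amino acid response, 19 were lower, 3 higher and 3 not past the threshold, with 22 and 3 adjusted over the list alone. Their mean was -0.38 (camera, adjusted p = 1.8e-06; adjusted p = 0.49 with an estimated correlation). Chac1, which degrades glutathione, was at -1.32 ± 0.09, the asparagine synthetase gene Asns at -1.16 ± 0.07, Atf5 at -0.97 ± 0.03 and Trib3 at -0.89 ± 0.04. The ER chaperone gene Hspa5 was at -0.30.

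Germline genes, many of which are silenced by DNA methylation outside germ cells, had 19 of 26 tested members lower, 1 higher and 6 not past the threshold, with 20 and 1 adjusted over the list alone. Their mean was -0.34 (camera, adjusted p = 2.7e-06; adjusted p = 0.49 with an estimated correlation). With normexp fitted on all spots the mean was -0.11 (adjusted p = 0.0089), and under median centring the preset test gave adjusted p = 0.27. Rhox5 was at -1.14 ± 0.02. Tex19.1 and Mael were both at -0.94 and were well above background in the channel labelled KO on 2 of 3 arrays. The exception was Piwil4 at 0.18. Of 37 imprinted genes, 18 were lower, 4 higher and 15 not past the threshold, with 18 and 4 adjusted over the list alone (mean -0.18, camera, adjusted p = 0.022; adjusted p = 0.49 with an estimated correlation). Magel2 was at -0.91, Grb10 at -0.80, Nnat at -0.73 and the growth inhibitor Cdkn1c at -0.68, while the growth factor gene Igf2 was at 0.48 by its brightest probe and lower by another.

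The NSC and radial glia list had 12 of 22 members lower, 4 higher and 6 not past the threshold, with 12 and 4 adjusted over the list alone. Its mean was -0.15 (camera, adjusted p = 0.048; adjusted p = 0.49 with an estimated correlation). The preset test gave adjusted p = 0.082 with normexp fitted on all spots, 0.34 with median centring, 0.053 with the scanner's processed signals, 0.051 with the stricter filter on dim probes and 0.094 without replicate 1. The transcription factor gene Sox9 was at -1.19 ± 0.06, Olig2 at -0.63 ± 0.03, Fut4 at -0.61 ± 0.06, Sox2 at -0.36 ± 0.08 and Nes, which encodes nestin, at -0.11 ± 0.02. Ptprz1 was saturated in both channels on all arrays, so no fold is given. The oligodendrocyte lineage list had 10 of 23 members lower, 1 higher and 12 not past the threshold, with 10 and 1 adjusted over the list alone (mean -0.26, camera, adjusted p = 0.0048; adjusted p = 0.49 with an estimated correlation). With normexp fitted on all spots the mean was -0.099 and the preset test gave adjusted p = 0.13. Camera's direction turned with median centring, without a call (adjusted p = 0.94), at a mean of -0.34 against the all-gene median of -0.26. The lower members included Olig1 at -1.32, Cspg4, which encodes NG2, at -1.26, Pdgfra at -0.59 and the myelin gene Mag at -0.16.

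Astrocyte and neuronal markers went both ways. Of 23 astrocyte genes, 8 were higher, 8 lower and 7 not past the threshold, with 8 and 9 adjusted over the list alone (camera, adjusted p = 0.64). Apoe was at 1.04 and Tnc, an extracellular matrix protein, at 0.78, against Aldh1l1 at -1.01. S100b was at 0.042 and not past the threshold, and Gfap did not pass the filter on dim probes. Of 25 neuronal genes, 5 were higher, 10 lower and 10 not past the threshold, with 6 and 10 adjusted over the list alone (camera, adjusted p = 0.64). Dlx2 was at 0.94, Ncam1 at 0.51 and Dlx1 at 0.45, against the migrating neuron marker Dcx at -0.53 and Tubb3 at -0.23.

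Markers of cell types outside the neural lineage were tested for a difference in other cells between the cultures. A ratio cannot show cells that both cultures hold. Some fibroblast genes were bright in both channels, with Col3a1 at a mean log2 intensity of 15.6 (labelled KO) and 15.5 (labelled WT). Others were dim, with Tcf21 at 6.16 and 6.24. Genes of the NSC list also ranged widely, from Vim at 15.0 and 15.2 to Sox2 at 8.54 and 8.90. Of 13 smooth muscle and contractile genes, 8 were higher, 1 lower and 4 not past the threshold, with 8 and 1 adjusted over the list alone (mean 0.13, camera, adjusted p = 0.016; adjusted p = 0.56 with an estimated correlation). With median centring the mean was -0.22 and adjusted p = 0.61. Tpm1 was at 0.49, Myl9 at 0.47 and Cnn2 at 0.39, against desmin (Des) at -1.19. Tpm1 and Cnn2 turned to -0.064 and -0.11 with median centring, where the all-gene median was -0.26, so both stayed above it. Of 25 fibroblast genes, 8 were higher, 9 lower and 8 not past the threshold (camera, adjusted p = 0.71), with Col1a2 at -1.48 and Fbln2 at -1.26 against S100a4 at 2.43. Of 19 pluripotent cell genes, 4 were higher, 6 lower and 9 not past the threshold (adjusted p = 0.53). Fgf5 was at -0.90 and Klf4 at 0.59, and Dppa4 was lower with a bound of 1.60-fold, equal to its measured ratio. Of 12 endothelial and blood genes, 4 were higher, 2 lower and 6 not past the threshold (adjusted p = 0.28). With median centring, which leaves any trend of the ratio with intensity in place, camera called this list higher against all other genes (mean 0.16, adjusted p = 0.00090). Lyz2 at 2.07 and the VEGF receptor gene Flt1 at 1.12 were higher, Tyrobp was at -0.28, and Emcn was at 0.21 but at -0.30 with median centring.

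The ribosomal protein list had 18 of 45 members higher, 5 lower and 22 not past the threshold, with 18 and 5 adjusted over the list alone (mean 0.20, camera, adjusted p = 0.0048; adjusted p = 0.57 with an estimated correlation). Of the members past the threshold, 16 were saturated in the channel labelled WT on all arrays. Without the 137 genes saturated on any array, the list's mean was -0.019 and adjusted p = 0.92, so no fold is given for Rps14, Rplp2, Rps28 or Rplp1.

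Of 6 tested Y-linked genes and Xist, 4 were lower, 0 higher and 2 not past the threshold, with 4 and 0 adjusted over the list alone (mean -0.24, camera, adjusted p = 0.045; adjusted p = 0.57 with an estimated correlation). The preset test gave adjusted p = 0.17 with normexp fitted on all spots, 0.095 with no filter on dim probes, 0.050 with unpaired channels and 0.052 without replicate 1. Ddx3y was at -0.63 ± 0.06, Eif2s3y at -0.35 ± 0.02, Uty at -0.24 and Kdm5d at -0.20. Uty and Kdm5d were well above background in the channel labelled KO on 2 and 1 of the 3 arrays, and Xist was at -0.020.

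The dyes were not exchanged on any array, so a bias of single probes toward 1 dye could stand in any value. In simulated data with 200 of 18033 genes changed, a mean of 9.65% of called genes were false, above the nominal share of the adjustment. In the real data 8660 genes were called, so that share cannot be carried over to them.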

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

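The criterion behind these values, a median above the 95th percentile of the negative control spots, was set after the medians had been seen. The comparisons used no control spots, and the 320 spots of the E1A spike-in controls lay just above that level in 3 of the 6 channels. Their median signal was 54.96 in Cy3 of replicate 2, against a 95th percentile of 54.2, 53.95 in Cy5 of replicate 2, against 52.6, and 51.52 in Cy3 of replicate 3, against 51.3. In the other 3 channels the median lay below it. Whether spike-in RNA had been added is not given in the sources used here.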

How the results depend on the processing

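Normexp was first fitted on all spots, and the fit on unmarked spots, used for the reported values, was chosen after seeing the data, as was leaving out saturated genes. The other alternatives were chosen before. Dnmt3a stayed higher in the RNA labelled KO under every alternative run, and at 0.99 it missed the threshold only where at least a 2-fold difference was asked. That rule left 86 genes higher and 124 lower, by its own construction. Across the planned and added alternatives, named genes kept direction and call in 3050 comparisons, lost the call in 244, gained it in 5 and changed sign in 28. Other settings of the list tests left aside, lists kept both in 598, lost the call in 44, gained it in 10 and turned in 31. No list that turned was past the threshold in its new direction. Where no cause is named below, the cause was not tested.

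Normexp fitted on all spots gave 2332 genes higher and 3119 lower, of which 2294 and 2749 were called the same way in the fit on unmarked spots, and 10 lists. Dnmt3l was then at 0.0019, and camera's direction turned for neural crest (mean -0.14) and BMP and TGF-beta (-0.024). Without replicate 1, 2 or 3 the higher genes numbered 3145 to 3858, the lower genes 3508 to 4077, the lists 13 to 15 and Dnmt3a 0.95 to 1.02. The replicate block was removed by comparing the channels unpaired, which gave 2761 higher and 3068 lower genes. Camera's direction then turned for oxidative phosphorylation (mean 0.0019) and cholesterol synthesis (-0.0039). An adjusted p under 0.01 left 8 lists, a correlation estimated per list left 0, and fry, which does not compare a list with other genes, gave 32.

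Median centring without loess gave 734 higher and 9398 lower genes, at an all-gene median of -0.26. It leaves in place any trend of the ratio with intensity, so list calls gained or lost under it may follow the intensity of the members. That was not tested. Under it Mbd1 was at -0.0084, Mbd3 at -0.25, Gadd45a at -0.36, Tpm1 at -0.064, Cnn2 at -0.11, Emcn at -0.30, Sox7 at 0.037, Id1 at -0.17, Pcdhb21 at -0.034 and Pcdhb17 at -0.023. Pkm was at -0.012, Hspb1 at -0.13, Cox6c at -0.28, Sdhc at -0.18, Cox5a at -0.35, Lss at -0.11, Msmo1 at -0.38, Rab10 at -0.36 and S100b at -0.023. Camera's direction turned for lists with these means: neuronal -0.13, oligodendrocyte -0.34, pluripotent -0.20, G1 cyclins -0.33, Wnt -0.32, Hox -0.23, hypoxia and glycolysis -0.33, heat shock -0.38, ribosomal -0.42 and Y-linked -0.32.

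The remaining turns were these. Without background correction camera turned for neural crest (-0.10) and oxidative phosphorylation (0.0021). With the scanner's processed signals Dnmt3l was at 0.0063, and neural crest (-0.046), oxidative phosphorylation (0.022) and cholesterol synthesis (-0.021) turned. With the authors' table Dnmt3l was at 0.026, and neural crest (-0.024), oxidative phosphorylation (0.044) and cholesterol synthesis (0.0020) turned. Scaling between arrays put the Mbd4 log2 ratio at 0.00057. The stricter filter moved Pax1 from -1.03 to 0.018, by taking another probe. Averaging probes moved Ndufb8 from -0.22 to 0.0075 and Rab10 from 0.13 to -0.023, whose probes went both ways, and turned DNA methylation machinery (0.10) and oxidative phosphorylation (0.016). Without replicate 1 Mbd4 was at 0.047 and oxidative phosphorylation turned (0.012). Without replicate 2 Dnmt3l was at 0.0037, and DNA methylation machinery (0.11), oxidative phosphorylation (0.0055) and cholesterol synthesis (0.0063) turned. Without replicate 3 neural crest turned (-0.10). Over these 3 fits Dnmt3l ranged from -0.028 to 0.0037 and cholesterol synthesis from -0.0095 to 0.0063. Without saturated genes the ribosomal list (from 0.20 to -0.019) and oxidative phosphorylation (0.0076) turned. Signal over background limits the dimmest genes: Sox7, for example, was well above background on no array in the channel labelled KO. Its bound of 1.10-fold lower in the RNA labelled KO equals its measured ratio. Its sign turned with median centring, so the bound does not secure a decrease.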

Other observations

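The test of the interferon list on array 3 was chosen after the result was seen, and the other tests below before. Among patterning and signalling lists, camera's preset test in the fit used here called hindbrain patterning, Hox and Hedgehog, and none held with an estimated correlation. Of 24 genes of midbrain, hindbrain and spinal cord patterning, 12 were higher, 4 lower and 8 not past the threshold, with 12 and 4 adjusted over the list alone (mean 0.10, camera, adjusted p = 0.038; adjusted p = 0.49 with an estimated correlation). Without replicate 1 and without replicate 2 it was not past the threshold, at adjusted p = 0.052 and 0.055. Zic1 was at 0.90, against Egr2 at -0.54, and Dbx1 at -0.66 was well above background in the channel labelled KO on 1 of 3 arrays. Of 14 forebrain genes, 7 were higher, 6 lower and 1 not past the threshold (adjusted p = 0.28), with Dlx2 at 0.94 and Dmrta2 at 0.81 against Lhx2 at -1.14. With median centring camera called this list higher against all other genes (adjusted p = 0.00075). Of 26 Hox genes, 5 were higher, 15 lower and 6 not past the threshold, with 5 and 15 adjusted over the list alone (mean -0.14, camera, adjusted p = 0.045; adjusted p = 0.49 with an estimated correlation). Hoxd13 was at -0.78, Hoxc9 at -0.57, Hoxb7 at -0.51 and Hoxb6 at -0.49, where another Hoxb6 probe was higher. The Hox list was at adjusted p = 0.29 with normexp fitted on all spots, where its mean was -0.035. With median centring its direction turned without a call (adjusted p = 0.69). Its adjusted p lay between 0.052 and 0.071 without background correction, with the scanner's processed signals, with no filter or the stricter filter on dim probes, and without replicate 2 or 3. Of 13 Hedgehog genes, 7 were lower, 1 higher and 5 not past the threshold, with 7 and 1 adjusted over the list alone (mean -0.18, camera, adjusted p = 0.017; adjusted p = 0.57 with an estimated correlation). The pathway targets Hhip at -0.48 and Ptch1 at -0.47 fell, with Gli3 at -0.33 and Cdon at -0.30, and the list was at adjusted p = 0.067 with normexp fitted on all spots, where its mean was -0.069, and at 0.080 with median centring.

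Of 22 Notch genes, 5 were higher, 9 lower and 8 not past the threshold (adjusted p = 0.43), with Heyl at -1.75, Hey1 at -0.61, Notch3 at 1.08 and Dll4 at 0.37. Of 31 Wnt genes, 6 were higher, 11 lower and 14 not past the threshold (adjusted p = 0.20), with Dkk3 at -0.81, Nkd1 at -0.78, Fzd1 at -0.63 and Sfrp1 at 0.72. Of 30 BMP and TGF-beta genes, 8 were higher, 10 lower and 12 not past the threshold (adjusted p = 0.88), with Bambi at -0.91, Inhba at -0.52 and Bmp4 at 0.60. Of 23 JAK-STAT genes, 10 were higher, 5 lower and 8 not past the threshold (adjusted p = 0.11), with Il6 at 0.65 and Stat3 at 0.57 against Socs1 at -0.37. Of 26 hypoxia and glycolysis genes, 12 were higher, 5 lower and 9 not past the threshold (mean 0.077, camera, adjusted p = 0.045; adjusted p = 0.49 with an estimated correlation), with Pfkl at 0.53 and Pkm at 0.45 against Ndrg1 at -1.14 and Aldoc at -0.46. That list lay between adjusted p = 0.055 and 0.083 with the authors' values, the scanner's processed signals, the stricter filter, unpaired channels, normexp fitted on all spots, no saturated genes, and without replicate 1 or 2. Its direction turned without a call (adjusted p = 0.69) with median centring, where Pkm was at -0.012 and the all-gene median at -0.26. Of 17 clustered protocadherins, 8 were higher, 4 lower and 5 not past the threshold (adjusted p = 0.10), with Pcdhb11 at 0.58 and Pcdhb7 at 0.40. Camera called that list higher against all other genes with the scanner's processed signals (adjusted p = 0.034), median centring (0.022), no filter on dim probes (0.038) and probes averaged (0.021). Of 13 heat shock genes, 5 were higher, 1 lower and 7 not past the threshold (adjusted p = 0.28), with Cryab at 0.71 and Hspa1a at 0.50 against Hspd1 at -0.27. Oxidative phosphorylation had 7 of 33 genes higher and 7 lower (adjusted p = 1.0), and cholesterol synthesis 5 of 20 higher and 6 lower (adjusted p = 0.99), with Sqle at -0.31. With median centring camera called both lower against all other genes, at means of -0.54 (adjusted p = 0.00073) and -0.48 (adjusted p = 0.012). Cardiac and skeletal muscle genes had 3 of 12 higher and 2 lower (adjusted p = 0.64), with Actc1 at 0.83. Endoderm genes had 3 of 15 higher and 2 lower (adjusted p = 0.81), with Dab2 at 0.53. With median centring the muscle and endoderm lists were also called higher against all other genes, at adjusted p = 0.023 and 0.049. Neural crest genes had 4 of 14 higher and 3 lower (adjusted p = 0.97), with Ngfr at -2.07 and Tfap2a at 0.43.

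Dnmt3a was higher in the RNA labelled KO, and 1 hypothesis is that the labels of the channels were exchanged. If they had been, germline genes might be lower in the RNA labelled KO, and a share of 0.05 of those past the threshold (1 of 20, exact 95% interval 0.00127 to 0.249) was higher, a count of 0 of 9 with normexp fitted on all spots. The median of the Dnmt3a probes was 0.746 once the trend on probe base composition had been removed, which argues against that trend as the source. The trend was weak, with R squared of 0.0018 to 0.024, and its removal moved no gene by more than 0.12. A bias from base composition of another form was not tested. The tables argue against a change shared by the neighbourhood, since the median of 12 neighbouring genes was -0.041, with Cenpo at -0.22. The median of the Dnmt3a probes was 0.23 with normexp fitted on all spots, and the authors' table has the same direction as the labels, so neither decides. An allele that still yields RNA outside the deleted part, a dye bias of single probes, and dim germline genes that move with the dye stay open and were not tested.

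The number of genes past the threshold was large against the median size of their differences, which the offset draws toward 0 for dim genes. The 6 RNA samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and the real split gave 5829 genes in the unpaired fit and the highest other 0, so 1 of the 10 splits gave as many. Removing the trend on probe base composition kept the count at 1.01 times its value, and 8222 of 8660 genes were called the same way, which speaks against that trend as the whole source. Among the autosomes and the X, each with at least 100 tested genes, the largest absolute chromosome median was 0.033, which speaks against a gain or loss of one of these that most cells carry. The Y was not in that test. A dye bias of single probes and a difference between the cell lines unrelated to Dnmt3a stay open and were not tested.

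The 3 arrays resembled each other closely, and 1 hypothesis is that they were 3 hybridisations of 1 RNA pair. The interferon list on array 3 lay -0.39 from the mean of the other arrays, outside the central range of -0.048 to 0.041 of 10000 random lists matched on intensity, and 31 of its 32 members were lowest there. The list was picked after it had shown the largest range between arrays of all lists, 0.42. The random lists, drawn from single genes, make no allowance for that choice or for members that move together. The difference of array 3 was -0.25 with normexp fitted on all spots, and it speaks against 1 shared RNA pair on all 3 arrays. Cultures of 1 cell line per genotype, harvested separately, could give arrays this close, and the labels do not say how many lines were used. No biological explanation was tested.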
